A study of Arabidopsis thaliana with 8 samples.

How the data were processed

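RNA from inflorescences of *Arabidopsis thaliana*, accession Ws, was hybridised to Affymetrix ATH1 arrays, with 1 labelled RNA per array. Per the labels' protocols, plants grew in compost in a greenhouse at 18 °C with 16 h of light, were harvested at growth stage 6.0, and 10 plants were pooled. The 8 arrays fall into 4 groups of 2 by their titles. CON is the control. T13 has a T-DNA insertion in AT3G47620 (TCP14) and T14 has one in AT1G69690 (TCP15). HET is heterozygous for an insertion at each of these genes. The labels do not give the zygosity of T13 or T14. The second HET array is titled as a repeat. Replicates were numbered in accession order, so the numbers name arrays and do not pair them. Nothing in the labels says whether the 2 arrays of a group came from separate pools of plants, so the p-values measure the spread between these arrays, which may be technical.

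The deposited table holds 1 intensity per probe set and array on a linear scale, for 22810 probe sets. The summary software is not given in the sources used here. The mean of each array, with 2% trimmed on each side, was 100, so the deposited intensity values already shared a scale and were not scaled again. Array medians lay between 51.35 and 59.5. No detection calls were used. The number of arrays limits the precision.

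Names came from the platform annotation, updated through Entrez identifiers to the symbols of a RefSeq table of assembly TAIR10.1. Of the 22810 probe sets, 13513 had 1 gene, 503 had several and 8794 were not listed and stay unnamed here, among them the 64 control probe sets. Of those with 1 gene, 13436 matched a locus tag. No coordinates are printed, because the files name no genome build. No gene was named from a probe set with several genes, except where stated.

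For the tests, 16 was added to each intensity and log2 was taken, so every log2 fold change is on the log2(intensity + 16) scale and understates the change of dim genes. A probe set was kept when it reached the 40th percentile of its own array in at least 2 arrays. Control probe sets were left out. This kept 15045 probe sets, of which 8286 had 1 gene, 280 had several and 6479 were unnamed. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with all 8 arrays sharing 1 estimate of the spread. The residual degrees of freedom were 4 and the prior degrees of freedom 7.39. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a probe set was called at an adjusted p under 0.05. The 5 comparisons were T13, T14 and HET each against CON, T13 against T14, and HET against the mean of T13 and T14. A moderated F test covered any difference among the 4 groups. On simulated data for T13 against CON with 15045 probe sets, the fit recovered 33 of 100 probe sets changed 2-fold and 93 of 100 changed 4-fold, with 2 false calls.

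Before the data were examined, 19 gene lists, the tests, the alternatives and the rule for named genes were fixed. The rule named TCP14 and TCP15 always. Next it took, from kept probe sets of 1 gene that passed the threshold with the arrays of the groups fully separated, the 10 largest rises and 10 largest falls. For T13 against T14 and for HET against the mean of T13 and T14, it took 5 and 5. Where fewer than 10 passed, the 10 smallest unadjusted p-values were added as values that did not all pass. Last, it took up to 4 members of each list with the smallest p. The lists held 397 genes, of which 60 had a named probe set and 39 were kept. Lists with at least 5 kept members were tested with limma's cameraPR at a preset inter-gene correlation of 0.01, and again with camera at an estimated correlation and with fry. The auxin response list alone reached that minimum. The 2 further lists, pollen wall enzymes and signals and tapetum and pollen coat, were written after the fits had been looked at. Of their genes, 25 of 38 and 11 of 25 had a named probe set, against 60 of 397 in the fixed lists. All 25 kept pollen wall genes had a negative log2 difference from CON in T13 and in HET. Tests of both lists are therefore not independent evidence of a direction or of its size.

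Alternatives covered the pseudocount (1 and 32), the filter (none, and the 60th percentile), quantile normalization, median centring, the variance prior, array weights, fits of the compared groups alone, the scanner background average from the labels as a covariate, and leaving out each array in turn. The log2 ratio of the 5' to the 3' GAPDH control probe set as a covariate, and list tests without the filter, were added after the data had been seen. No probe set named for TCP14 was found, so its level was not analysed here. Figures were drawn with matplotlib 3.10.9.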

Results

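The transcriptomes of inflorescences were measured on 8 ATH1 arrays, 2 for each of 4 groups. These were a control (CON), a line with a T-DNA insertion in TCP14 (T13), a line with one in TCP15 (T14), and plants heterozygous for an insertion at each gene (HET). A T-DNA insertion is a stretch of bacterially transferred DNA that can disrupt the gene it lands in. TCP14 and TCP15 encode related plant transcription factors. Rank correlations of intensity between arrays of the same group ran from 0.911 to 0.941 over 4 pairs, and those between arrays of different groups from 0.871 to 0.941 over 24 pairs. HET replicate 1 stood apart in the ratio of the 5' to the 3' GAPDH control probe set, at 0.345 against 0.0639 to 0.129 on the other 7 arrays. The 5' signal lay below the 3' signal on all 8 arrays, so each showed 3' bias, the least on HET replicate 1. Its ratio for the actin control probe sets was also the highest, at 0.267 against 0.0741 to 0.152. Its control probe set for 25S rRNA was the lowest, at 199.2 against 687 to 3321.9. The control probe set named for the 3' end of cre was also lowest there, at 3366.9 against 4068.8 to 7032.4. The GAPDH ratio as a covariate therefore need not cover all that sets this array apart. The scanner background average was 98.49 and 111.86 on the T13 arrays and 112.87 on CON replicate 1, against 83.50 to 87.36 on the rest. A moderated F test in limma found 150 of 15045 probe sets that differed among the 4 groups.

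The targeted genes were examined first. The intensity of TCP15 was 221 ± 32.4 in CON (SD, n = 2), 205 ± 1.27 in T13, 77.4 ± 12.2 in T14 and 205 ± 23.8 in HET. Both T14 arrays, at 86 and 68.8, lay below all 6 other arrays. T14 against CON gave a log2 difference of -1.34 (SE 0.2), which did not pass over all probe sets (limma adjusted p = 0.0606). T13 against T14 gave 1.25 (SE 0.2), which passed (limma adjusted p = 0.0244), although not in 7 of 20 alternatives. HET against CON gave -0.10 (limma adjusted p = 0.994). No fall of TCP15 was thus measured in HET. A heterozygous insertion need not lower it, and the labels do not place the insertion relative to the probes, so this level does not establish the HET genotype. TCP14 was not analysed here, so the arrays do not check the T13 label or the TCP14 part of the HET label.

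The first comparison set T13, the line with an insertion in TCP14, against CON. With a single line per gene, an effect of the insertion cannot be told apart from other differences of that line. Among the named genes that fell in T13 were 4 that act on pectin or belong to a family that does. This grouping was made after the values were seen and was not tested. The pectinesterase AT3G17060 dropped from 149 ± 10.5 in CON to 17 ± 13.8 (SD, n = 2 each), a log2 change of -2.38 (SE 0.276, limma adjusted p = 0.00412). The pectinesterase AT5G07420 changed by -2.58, with intensities of 66.1 and 175 in CON against 6.2 and 3.8. AT1G10770, of the invertase and pectinesterase inhibitor family, fell from 600 ± 38.6 to 124 ± 3.18, and the polygalacturonase AT3G07820 from 768 ± 20.7 to 175 ± 15.1. The other named falls were AT1G52680 (log2 -2.38), AT1G04470 (-2.14), AT5G55070, a subunit of the 2-oxoglutarate dehydrogenase complex (-2.14), AT3G28830 (-2.08), AT3G26110 (-2.06) and AT5G39880 (-1.97). AT5G55070 passed in 6 of 20 alternatives (limma adjusted p from 0.00135 to 0.357). It did not pass without CON replicate 1 (log2 -2.196), CON replicate 2 (-2.074), T13 replicate 2 (-1.273) or either HET array (-2.135).

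In all, 89 probe sets passed in T13 against CON, 88 lower and 1 higher, and 901 had an unadjusted p under 0.05 where chance gives 752. The riser was AT5G01080, at 88.5 and 191.3 in T13 against 22.5 and 5.9 in CON (log2 2.34, limma adjusted p = 0.0291). It passed in 11 of 18 alternatives. None of the 39 kept members of the fixed lists passed, the 2 of the late pollen list included. ANX2, a receptor-like kinase that keeps pollen tubes intact, had a log2 difference of -1.48 (limma adjusted p = 0.111). The auxin-conjugating enzyme GH3.3 had -1.27 (limma adjusted p = 0.462), and from -1.726 to -0.819 over 20 alternatives. Adjusted over the list alone, 2 of the 39 passed, 1 in the late pollen list and 1 in the auxin response list. The 15 lists with kept members held from 1 to 5 each, so this adjusts little, and for a list of 1 not at all. Without the filter, 46 probe sets passed. Leaving out CON replicate 1, CON replicate 2, T13 replicate 1 or T13 replicate 2 left 37, 15, 43 and 33.

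**Figure D1:**
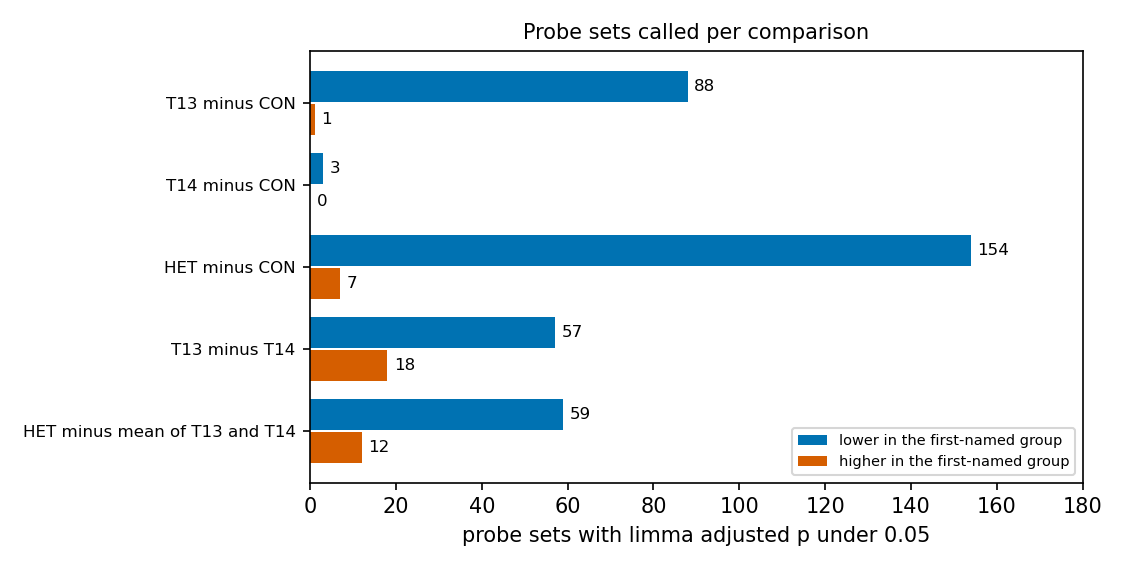
Number of probe sets with a limma adjusted p under 0.05 in each of the 5 comparisons, split into those lower and higher in the first-named group. Falls outnumber rises in each comparison, from 3 against 0 in T14 minus CON to 154 against 7 in HET minus CON.

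The second comparison set T14, the line with an insertion in TCP15, against CON. In T14, 3 probe sets were lower than in CON and 0 were higher (limma), while 875 had an unadjusted p under 0.05 where chance gives 752. AT1G23960 fell from 100.3 and 100.2 in CON to 2.5 and 5.7 in T14 (log2 -2.54, limma adjusted p = 0.0341). AT1G68875 fell from 253 ± 8.56 to 44.3 ± 4.17 (SD, n = 2; log2 -2.16, limma adjusted p = 0.0341). The remaining probe set reads several genes of 1 family, among them AT1G25150 and AT1G24800, and is named here after its values were seen. ATA27, a beta-glucosidase of the tapetum, the cell layer that feeds developing pollen, had 209 ± 1.91 in CON and 67.4 ± 6.36 in T14 and did not pass (log2 -1.43, limma adjusted p = 0.0606). Other small p-values that did not pass were those of DI21 (log2 -1.79), AT3G05500 (-1.96), AT1G73490 (-1.79), AT1G65370 (-1.55), AT1G21770 (-1.40) and AT5G48760 (-1.04), with limma adjusted p from 0.13 to 0.178. Of the fixed lists, 0 of 39 kept members passed in limma, and adjusted over the list alone 2 did, TCP15 and 1 tapetum gene. TCP15 is the only kept member of its list, so its p was not adjusted there. No probe set passed with a pseudocount of 1, without the filter, with scanner background as a covariate, without CON replicate 1 or without T14 replicate 1. There were 5 without T13 replicate 1 and 1 without CON replicate 2.

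The third comparison set HET against CON. Named falls included AT3G17060 at 8.95 ± 2.33 (log2 -2.72), AT3G07820 at 105 ± 2.47 (-2.69), AT5G07420 at 2.95 ± 1.06 (-2.73) and the polygalacturonase AT5G48140 with a log2 change of -2.72 (SD, n = 2; limma adjusted p from 0.000219 to 0.00215). Further falls were AT5G47350 (log2 -3.27), AT1G54070 (-3.06), AT1G04470 (-2.83), AT5G39880 (-2.77), AT3G26110 (-2.73) and AT1G78460 (-2.72). AT5G47350 passed in 8 of 20 alternatives (limma adjusted p from 0.000125 to 0.549), and not without CON replicate 1 (log2 -3.834), CON replicate 2 (-2.706), HET replicate 1 (-3.18) or HET replicate 2 (-3.361). ANX2 fell from 63.4 ± 2.47 to 6.95 ± 3.75 (log2 -1.80, limma adjusted p = 0.0202). The 6 named rises were AT1G12010, an ACC oxidase of ethylene synthesis (log2 2.25), the peroxidase AT4G36430 (1.44), AT5G48210 (1.19), ATA27 (1.15), AT5G20700 (1.15) and AT5G16920 (0.99). ATA27 stood at 488 ± 114 in HET against 209 ± 1.91 in CON. These calls were less firm than most of the falls: of the alternatives, AT1G12010 and ANX2 each passed in 12 of 19, and of 20 AT4G36430 passed in 14, AT5G48210 and ATA27 in 15, AT5G16920 in 13 and AT5G20700 in 10. None of these 7 passed without CON replicate 2 (log2 1.045 to 2.121 for the rises, -1.767 for ANX2) or HET replicate 1 (0.916 to 2.57, -1.632). Without CON replicate 1 (0.932 to 2.372, -1.831) AT4G36430 passed, and without HET replicate 2 (0.963 to 1.923, -1.966) AT5G48210 and ATA27 did.

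Of 161 probe sets that passed in HET against CON, 154 were lower and 7 higher, and 958 had an unadjusted p under 0.05 where chance gives 752. In the fixed lists 1 of 39 kept members passed, ANX2, and adjusted over the list alone 4 did. GH3.3 had a log2 difference of -1.68 (limma adjusted p = 0.0893) and DFR, an enzyme of anthocyanin synthesis, -1.26 (limma adjusted p = 0.0761). The auxin response list, with 5 kept genes, had a mean log2 of -0.51 and passed with the preset correlation (limma cameraPR adjusted p = 0.0387). It did not pass with an estimated correlation (adjusted p = 0.235). The array with the high GAPDH ratio belongs to this group. With that ratio as a covariate 52 probe sets passed, and without HET replicate 1, HET replicate 2 or CON replicate 2 there were 86, 104 and 103. With scanner background as a covariate 102 passed.

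**Figure D2:**
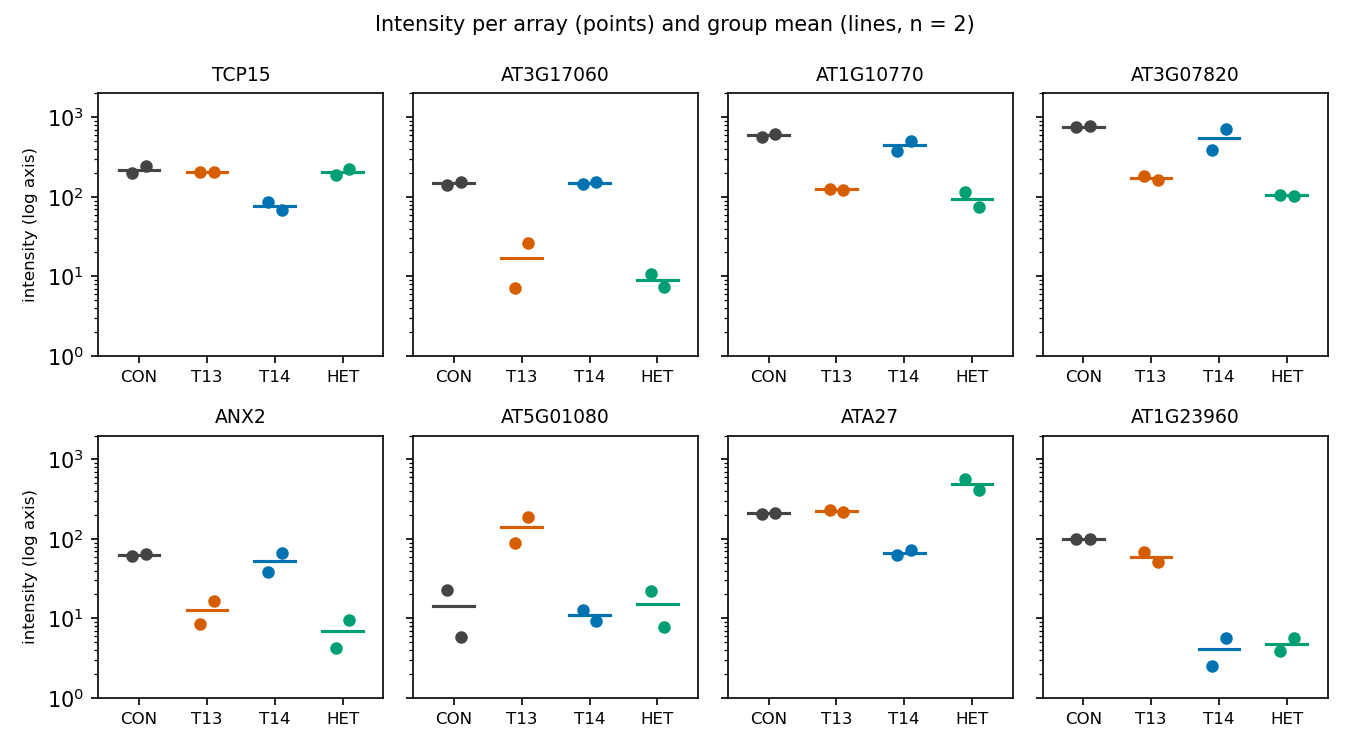
Intensity of 8 genes on each array (points, log axis) with the group mean (lines, n = 2), for the 4 groups. TCP15 lies lowest in T14, ANX2 and the pectin genes AT3G17060, AT1G10770 and AT3G07820 lie low in T13 and HET, and AT1G23960 lies near the bottom of the scale in T14 and HET.

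The falls in T13 and HET overlapped. Of 88 probe sets lower in T13, 85 were also called lower in HET, against 0.901 for independent lists, a value that leaves out the shared controls. In 100 simulations of unchanged groups sharing these controls the overlap was 0.06, but such groups have almost no calls, so this is no baseline for lists of this length. Part of the excess may come from the shared CON arrays, which are too few to split. Of the 3 probe sets lower in T14, 2 were also called lower in HET, against 0.0307 for independent lists. In T13, 0 of these 3 were called lower, against 0.0175. Across genes, the log2 differences from CON had a covariance of 0.0626 for T13 and HET (0.0329 in the simulations), 0.0584 for T13 and T14 (0.0328) and 0.0379 for T14 and HET (0.0328). The correlations were 0.517 (0.501), 0.573 (0.5) and 0.341 (0.5). HET against T13 called 0 probe sets in limma, with 1491 at an unadjusted p under 0.05 where chance gives 752. Of the 88 probe sets lower in T13, 78 had a still lower mean in HET, with a median log2 difference of HET from T13 of -0.49. Of the 154 probe sets lower in HET, a set chosen by a contrast that leaves out T13 and T14, 139 had a lower mean in T13 than in T14. Their median log2 difference was -1.15, against 0.0193 over all kept probe sets, and limma called 56 lower and 4 higher in T13. Of 25 measured genes in a list of pollen wall enzymes and signals that was written after the fits had been seen, 22 were called lower in T13, 23 in HET and 0 in T14 (limma).

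**Figure D3:**
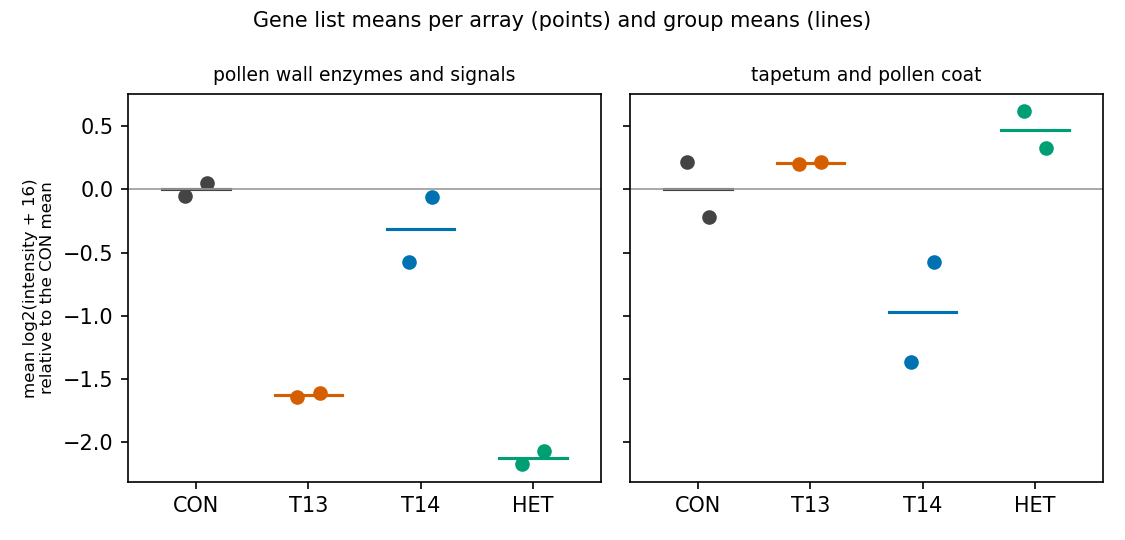
Mean log2(intensity + 16) of the pollen wall list (25 genes) and the tapetum list (9 genes) on each array, relative to the CON mean; points are arrays and lines group means (n = 2). The T13 and HET arrays lie lowest for the pollen wall list, and the T14 arrays lie lowest for the tapetum list.

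The 2 single-gene lines were then compared directly. Lower in T13 were AT3G17060 (log2 -2.40), AT5G07420 (-2.33), AT1G04470 (-2.07), the protein kinase AT3G20530 (-2.0) and the carboxypeptidase-like gene scpl38 (-1.86). Higher in T13 were AT5G01080 (2.44), AT1G68875 (2.44), AT1G23960 (1.91), DI21 (1.65) and ATA27 (1.54). Of the fixed lists TCP15 passed, and the tapetum gene A9 (AT5G07230) had a log2 difference of 1.76 that did not (limma adjusted p = 0.172). That value was 0.99 without T14 replicate 1 and 2.529 without T14 replicate 2. Of 75 probe sets that passed, 57 were lower and 18 higher in T13. At an unadjusted p under 0.05 there were 653, fewer than the 752 that chance gives. The count fell to 0 without the filter and with scanner background as a covariate (limma, with 1122 and 450 at an unadjusted p under 0.05), to 4 when these 4 arrays were fitted alone, and to 38 with the GAPDH ratio as a covariate. Dropping the filter or fitting these arrays alone leaves the group means as they are, and without the filter 22746 probe sets were tested. Over the 75, the median size was 1.45 and the median SE 0.35 with the background covariate, and 1.51 and 0.231 with the GAPDH ratio, against 1.48 and 0.24. Leaving out T13 replicate 1, T13 replicate 2 or T14 replicate 2 left 8, 9 and 15. Leaving out CON replicate 1, CON replicate 2, HET replicate 1 or HET replicate 2, which alter the shared spread, left 45, 44, 35 and 41.

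The last comparison set HET against the mean of T13 and T14. ATA27 was higher in HET (log2 1.81, limma adjusted p = 0.00282), as were AT5G48210 (1.57), AT5G22430 (1.31) and AT5G16920 (1.05). Lower in HET were AT1G54070 (-2.25), AT2G15880 (-1.82), AT1G19500 (-1.71), AT5G48140 (-1.71) and AT5G50830 (-1.69). In all 71 probe sets passed, 12 higher and 59 lower, and 1866 had an unadjusted p under 0.05 where chance gives 752. None of the 39 kept list members passed, and 6 did adjusted over the list alone. The expansin EXPA4, a cell wall loosening protein, had a log2 difference of 1.1 (limma adjusted p = 0.158). Without HET replicate 1, the array with the high GAPDH ratio, or with that ratio as a covariate, 0 probe sets passed (limma, with 534 and 296 at an unadjusted p under 0.05). Over the 71, the median size was 1.31 and 1.13 against 1.41 and the median SE 0.261 and 0.347 against 0.208, so the median size fell and the median SE grew. ATA27, for example, had 1.58 (SE 0.203) without that array and 1.47 (SE 0.288) with the covariate, against 1.81 (SE 0.18). The count was 134 without T14 replicate 1, 3 without the filter and 4 with scanner background as a covariate.

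In the remaining fixed lists no kept member passed in any of the 5 comparisons. These were the cell cycle (3 kept genes), cytosolic ribosomal proteins (4), gibberellin (2), auxin response (5), cytokinin (2), gynoecium and organ boundary (3), cell wall loosening (4), flavonoid and anthocyanin (2), jasmonate and wound (1), cold and water stress (3), circadian clock (1), tapetum (2) and photosynthesis (4) lists. In T13 against CON, the kinase AUR1 of the cell cycle list had a log2 difference of -0.34, the gibberellin receptor GID1A 0.38, the cytokinin response regulator ARR15 0.62, SPT of the gynoecium list 0.32, COR15A of the cold list -0.36 and RCA of the photosynthesis list -0.13 (limma adjusted p from 0.823 to 0.93). Over the alternatives the sign turned for SPT (-0.027 to 0.671), COR15A (-0.532 to 0.024) and RCA (-0.293 to 0.037), while AUR1, GID1A and ARR15 kept theirs. The floral identity, salicylate, heat shock and seed lists had 0 kept members, so nothing was tested there.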

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

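The tests of explanations in this part were chosen after the results had been seen. The test of T13 against T14 marked 75 probe sets as different between the lines. Among the named ones, TCP15 differed by 1.25 on the log2 scale, AT3G17060 by -2.40, AT5G07420 by -2.33, AT1G04470 by -2.07, AT3G20530 by -2.0 and scpl38 by -1.86. AT5G01080 and AT1G68875 each differed by 2.44, AT1G23960 by 1.91, DI21 by 1.65 and ATA27 by 1.54. The ratio of the 5' to the 3' GAPDH control probe set, which the comparisons do not use, was 0.345 on HET replicate 1, above both CON arrays at 0.086 and 0.129.

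The list of pollen wall genes lay lower in T13 and HET than in CON. With the GAPDH ratio as a term, the list's mean difference from CON stayed at -1.70 in T13 and -2.01 in HET, and with scanner background as a term at -1.61 and -2.17, each against -1.63 and -2.12 without. These values argue against RNA 3' bias or scanner background as the whole cause. An equal dilution of all pollen transcripts, as from fewer late pollen grains in the harvest, was read from a ratio. This was the SD of the log2 ratios over their standard error, which 1 shared factor would put near 1 if genes erred independently. The estimated correlation between genes of the list was 0.473, which would put it lower, and the members were chosen after their falls were seen. In T13 the ratio was 1.05, 1.01 and 1.15 for pollen wall genes with a CON mean of at least 150, 200 and 300. It was 1.91 at 100, the minimum first tried. That minimum takes in genes at the array floor such as AT5G07420, and it was raised after this value was seen. With all members, added later, that averaged at least 16 in T13 the ratio was 1.41, and 1.6 with the late pollen list. TUA1 of that list went from 143 to 102 (log2 -0.521 with no pseudocount) against a mean of -1.86 at 150. ANX2 of the same list, at 12.7 in T13 and 6.95 in HET, fell under that limit of 16 and was left out. In T13 an equal dilution therefore stays undecided, since these sets disagree and TUA1 is 1 gene. In HET the ratio was 2.41 with both lists and 1.73 at 300, a wider spread than 1 shared factor gives by these standard errors. Those errors come from 2 arrays per group whose spread may be technical, so they cannot decide on an equal dilution there. A loss weighted to later stages, and an effect of the insertions themselves, were not tested.

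A control probe set named for U12639 was higher in the insertion lines. Its intensity was 10.9 in CON, 24.4 in T13, 106 in T14 and 37.8 in HET (means, n = 2). The CON level is at the array floor, so a fold can be given as a bound alone: with intensities under 16 set to 16, the log2 difference of T14 from CON was at least 2.72. What this probe set detects is not given in the sources used here. Of the 63 other control probe sets, 37 lay above that floor on all CON and T14 arrays. Their median log2 difference of T14 from CON was 0.373 (interquartile range 0.792) and the highest was 1.22. These values argue against a joint shift of the control probe sets as the whole cause of the U12639 difference. A smaller joint shift is not excluded, since the median itself was positive. The test was first run on all 63. In 4 of the 64 control probe sets all 6 insertion arrays lay above both CON arrays, an order that chance gives in 3.57% of cases, and 0.036 is the smallest p an exact one-sided permutation test can give here. Sequence carried by the insertions stays open and was not tested.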

How the results depend on the processing

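Over all alternatives, 742 of 993 values of named genes that had passed were still past the threshold, and 15 of 3836 that had not passed came to pass. Many alternatives leave the group means as they are, and the passing genes were taken with their arrays fully separated, so their directions were largely fixed. Quantile normalization, median centring and the 2 covariates can turn a direction. Under these, 200 of 200 values that had passed and 704 of 780 that had not kept their direction. The passing differences were large and the arrays already shared a scale, so median centring and quantile normalization could hardly turn them. Where fewer arrays or more probe sets were tested, the threshold itself moved, and otherwise the cause was not tested. With 1 array left in a group, that array is assumed to vary like the other groups. Leaving out each array in turn gave 15 to 108 calls for T13 against CON, 0 to 5 for T14 against CON, 86 to 184 for HET against CON, 8 to 74 for T13 against T14, and 0 to 134 for HET against the mean of T13 and T14. The F test stayed within 1.5 times of its 150 calls throughout. Without the filter, the calls were 46 for T13 against CON, 0 for T14 against CON, 0 for T13 against T14 and 3 for HET against the mean. With scanner background as a covariate they were 0 for T14 against CON, 102 for HET against CON, 0 for T13 against T14 and 4 for HET against the mean. With the GAPDH ratio as a covariate, chosen after seeing the data, they were 52 for HET against CON, 38 for T13 against T14 and 0 for HET against the mean. For T14 against CON, a pseudocount of 1 gave 0, quantile normalization 5, no trend 1, a robust prior 6 and the compared groups alone 7. For T13 against T14, the compared groups alone gave 4. At an unadjusted p under 0.05 limma still had 857, 1306 and 450 probe sets for T14 against CON with a pseudocount of 1, without the filter and with the background covariate. The 85 probe sets lower in both T13 and HET became 45 without the filter, 42 with the GAPDH ratio and 15 without CON replicate 2. Of the list tests, 1 passed as planned; the estimated correlation, fry directional, fry mixed and quantile normalization gave 0, scanner background 2, no filter 4 (chosen after seeing the data), and leaving out an array 0 to 3. All alternatives fixed before the data were examined were run. Dim genes limit these arrays, since 15045 of 22810 probe sets passed the filter and falls to intensities under 16 are compressed.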

Other observations

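Both gene lists described first here, and the tests of this part, were chosen after the results had been seen. The p-values of both lists are therefore not independent evidence of a direction or of its size. The list of pollen wall enzymes and signals had 25 measured genes. All 25 had a negative log2 difference from CON in T13 and in HET. In T13 limma called 22 of them lower, and the mean log2 difference from CON was -1.63 (limma camera adjusted p = 0.00935 with an estimated correlation). In HET limma called 23 lower, and the mean was -2.12 (limma camera adjusted p = 0.0075 with an estimated correlation). In T14 0 were called by limma and the mean was -0.32 (adjusted p = 0.158 with an estimated correlation), moving to -0.059 without T14 replicate 1 and -0.573 without T14 replicate 2, where the list passed. With each array left out in turn, that adjusted p ran from 0.0185 to 0.427 (limma camera with an estimated correlation). The members included the expansin EXPB5, at 193 ± 16.1 in CON, 61.4 ± 2.19 in T13 and 49.8 ± 3.75 in HET (SD, n = 2), and the peptide genes RALFL25 and RALFL26. T13 lay below T14 by 1.31 on average (adjusted p = 0.0105 with an estimated correlation). The 5 measured genes of the late pollen list, which was fixed before the data were examined, had mean log2 differences of -0.83 in T13 and -0.88 in HET when the filter was left out. The adjusted p of those was 0.0466 and 0.0579 with an estimated correlation. Of these 5, 3 are too dim to pass the filter, and of the 2 kept members 0 passed in T13 and 1 in HET (limma).

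The 9 measured genes of the tapetum and pollen coat list had a mean log2 difference from CON of -0.97 in T14 (adjusted p = 0.0618 with an estimated correlation), 0.21 in T13 (0.537) and 0.47 in HET (0.148), none of which passed. The difference of 1.18 between T13 and T14 did pass (limma camera adjusted p = 0.0165 with an estimated correlation). It was 0.784 without T14 replicate 1 and 1.579 without T14 replicate 2, and did not pass without T13 replicate 1 (1.188). With each array left out in turn, its limma camera adjusted p ran from 0.0101 to 0.0535 with an estimated correlation. The T14 mean passed without T14 replicate 2 (-1.369), with limma camera adjusted p from 0.0185 to 0.143 over the same fits. The T14 arrays lay at -1.37 and -0.57 relative to CON, so replicate 1 carried the larger share. Without CON replicate 2 the T13 mean was -0.011 and the HET mean 0.252, and without CON replicate 1 the T13 mean was 0.432.

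Some genes were lower in both T14 and HET than in CON and T13. AT1G23960 stood at 59.8% of its CON mean in T13 and at the array floor in T14 and HET, which is at most 16% of CON with intensities under 16 set to 16. Contrasting T14 and HET with CON and T13, and leaving out TCP15 as a targeted gene, 11 probe sets of 1 gene had an unadjusted limma p under 0.001 with both T14 and both HET arrays below the 4 others. Of these, 7 were on chromosome 1, where 2.9 would lie by its share of the 8180 probe sets. A Fisher's exact test for that excess gave p = 0.0104 (one-sided), or 0.0624 when adjusted over 6 such tests, which does not pass. The other 5, from T14 and HET higher to the pairings of T13 with HET or T14, gave exact p from 0.395 to 1. All 6 asked about chromosome 1 alone. TCP14 is on chromosome 3, and an excess there in the pairing of T13 with HET was not tested. A first version of the test, without the rule on single arrays and with TCP15, had taken 11 of 17 on chromosome 1. Its Fisher's exact p was 0.00102, or 0.00612 when adjusted over 6 such tests. That version let in genes such as AT1G54070 and AT1G78460, which were higher in T14 than in T13, and TCP15, which was not low in HET. With the rule on single arrays and no limit on p, 124 probe sets (1.52%, where chance gives 1.43%) were lower. Of these, 50 were on chromosome 1 against 32.7 by its share (Fisher's exact p = 0.000468, not adjusted). The other 5 tests of this kind gave Fisher's exact p from 0.31 to 0.999. Fisher's test takes genes as independent, which genes measured on the same arrays need not be. TCP15 is on chromosome 1, and a candidate explanation is chromosome 1 sequence that the T14 and HET plants share and CON and T13 lack. The 7 genes run from AT1G03410 to AT1G73490, so a single short segment would not hold them all, and in T13 they stood at 33.9% to 115% of CON. Whether HET plants keep 1 expressed copy of the CON allele stays open: the median HET level over the 7 was 23.9% of CON, with members from 9.41% to 40.8%, and the genes were picked for low HET values. That reading was first taken on AT1G23960 alone, then on the first 11 (median 21.3%).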
